A study of Mus musculus with 6 samples.

How the data were processed

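Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse CD8+ T cells. Per the labels' protocols, the T cells were isolated from spleen by removal of other cells, activated with antibodies against CD3 at 5 µg/mL and CD28 at 1 µg/mL, and kept for 48 h in the lower chamber of a transwell, with tumour cells in the upper insert behind a porous membrane. Per the labels' protocols, the tumour cells were PD-1-resistant lung adenocarcinoma cells, either a control (Res-ctrl) or cells with a short hairpin RNA against Fabp7 (Res-shFabp7), and 3 biological replicates of each were sequenced with paired reads of 76 bases, at 35 to 75 M read pairs per library. The number of read pairs of each single library is not given in the sources used here.

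Per the submitters' processing notes, the tools were Trim Galore 0.6.5, cutadapt 2.8, Bowtie 1.1.2 and MACS2 2.2.7.1, and the genome build was mm10. Whether the reads were shifted for the transposase offset, how duplicates were treated and which MACS2 mode was used are not given in the sources used here. The authors deposited 1 peak list per library, so that peaks were called per library and not on pooled replicates. Each deposited list gives the position and summit of a peak, its p-value and q-value as −log10, its pileup, which is the coverage signal at the summit, and its fold, the ratio of the summit to the local background. These values are the authors' own for each peak and were used to describe, rank and filter peaks within a list. The weakest peak of each list has a q just under the 0.05 threshold, and the median −log10 q of a list is 12.2 to 14.8. The lists hold peaks on chromosomes 1 to 19, X and Y.

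Starts in the lists appear to count from 0, as inferred from the summit and end positions, and are given here counted from 1. The background of a peak was recovered from its pileup and fold, with 1 added to each side of the ratio as inferred from the values, and its most frequent value in a list served as a relative measure of depth. This measure was 1.03, 0.868 and 0.959 for the Res-shFabp7 libraries and 0.709, 0.608 and 1.01 for the Res-ctrl libraries. A shallower library yields fewer weak peaks, so the absence of a peak is not the absence of accessibility.

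Peaks of the 6 lists were merged into regions wherever they overlapped by at least 1 bp. A library held a region if any of its peaks overlapped it. A region called only with 1 group had a peak in 3 of 3 libraries of that group and in 0 of 3 of the other. For 1 region, Fisher's exact test on 3 against 3 libraries cannot go below 0.10, so no region was tested alone. Library values were compared by two-sided exact permutation tests, for which 3 against 3 cannot go below 0.10. Overlap was measured by the base-pair Jaccard index, the shared length over the joint length, in the 15 pairs of libraries, with a one-sided exact permutation of the groups.

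Gene positions came from a RefSeq gene table of GRCm38.p6, the same primary assembly as mm10, limited to 21887 protein-coding genes. Each peak, by its summit, and each region, by its midpoint, was assigned to the nearest gene within 100 kb. The table used here has neither strand nor exons. The planned share of peaks at promoters was therefore replaced by the share within 1 kb of either end of a gene, which mixes starts with 3′ ends, and exons, introns and UTRs are not given. The 19 gene lists hold 406 symbols, of which 401 matched the table. For each list, regions called only with Res-shFabp7 and only with Res-ctrl were compared with those of all other genes by Fisher's exact test, with Benjamini-Hochberg adjustment over the lists. Regions are not independent replicates, and these p-values describe the 6 libraries.

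The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each direction, the 10 genes whose group-specific region has the highest smallest −log10 q over its 3 libraries, with unnamed gene models left out. From each list it takes up to 3 genes per direction with the most group-specific regions. It adds Ifng, Gzmb, Pdcd1, Tcf7, Tox, Arntl and Fabp7 whatever their values. The result of 1 gene that the rule takes is not reported here. Alternatives were a stricter q of 0.01 or 0.001, equal numbers of peaks (the 82153 of highest −log10 q in each library, the length of the shortest list), other ways of merging and counting, leaving out each library, 10000 random gene lists matched on regions per gene, and a replicate block.

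After the data had been seen, lists of the strongest 40000 and 20000 peaks, a comparison with Res-ctrl replicate 3 alone and a gene distance of 20 kb were added. Group-specific regions were also counted by chromosome, by genome bin and by gene. Peak heights of the regions called in all 6 libraries were also compared across libraries, first as quantile-normalised log2 heights and then as normal scores of their ranks, both with limma and a trend of spread on height. That comparison sets the peaks' own values of different lists against each other and its calls depended on the settings, so the report does not use it. Its counts stand among the other observations.

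On simulated lists with 200 regions planted per direction among 134174, the merging recovered 200 and 200. Each planted region had a peak in every library of its group, so this checks the merging only and not peaks missed for depth. The list test, on 3273 group-specific regions with directions shuffled 200 times, called 0.01 lists per draw. With an odds ratio of 10 toward Res-ctrl planted in 1 list at a time, it recovered on average 72.0% of draws for the 2 lists with at least 10 group-specific regions and 24.6% for the other 17. A shift toward Res-shFabp7 was not simulated. In the height comparison over 56610 regions, 0.5% of 200 planted regions were recovered at a fold of 1.5 and 52.0% at a fold of 2. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.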

Results

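Accessible chromatin was profiled in activated mouse CD8+ T cells cultured for 48 h across a porous membrane from lung adenocarcinoma cells. The tumour cells were resistant to PD-1 blockade and carried either a control (Res-ctrl, 3 libraries) or a knockdown of Fabp7 (Res-shFabp7, 3 libraries). Fabp7 encodes a fatty acid binding protein. The knockdown was in the tumour cells, so the T cell libraries hold no check of it. No peak was assigned to Fabp7 in any of the 6 libraries. The comparison asked whether the open regions of the T cells differed with the tumour cells they were cultured with.

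T cells cultured with Res-shFabp7 had more called peaks. The Res-shFabp7 lists held 104575, 105796 and 100243 peaks and the Res-ctrl lists 84844, 82153 and 96310. The means were 103538 ± 2918 (SD, n = 3) and 87769 ± 7518 (SD, n = 3), a difference of 18.0% of the Res-ctrl mean, and the groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The peaks covered 25.7 ± 0.48 Mb with Res-shFabp7 and 21.5 ± 2.37 Mb with Res-ctrl (SD, n = 3 each; exact permutation p = 0.1). The relative depth of the lists, read from the background pileup, was 0.951 ± 0.0793 and 0.774 ± 0.207 (SD, n = 3 each; exact permutation p = 0.3), and Res-ctrl replicates 1 and 2 were the lowest. Against Res-ctrl replicate 3 alone, whose background of 1.01 lay within the Res-shFabp7 range, the difference was 7228 peaks.

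**Figure D1:**
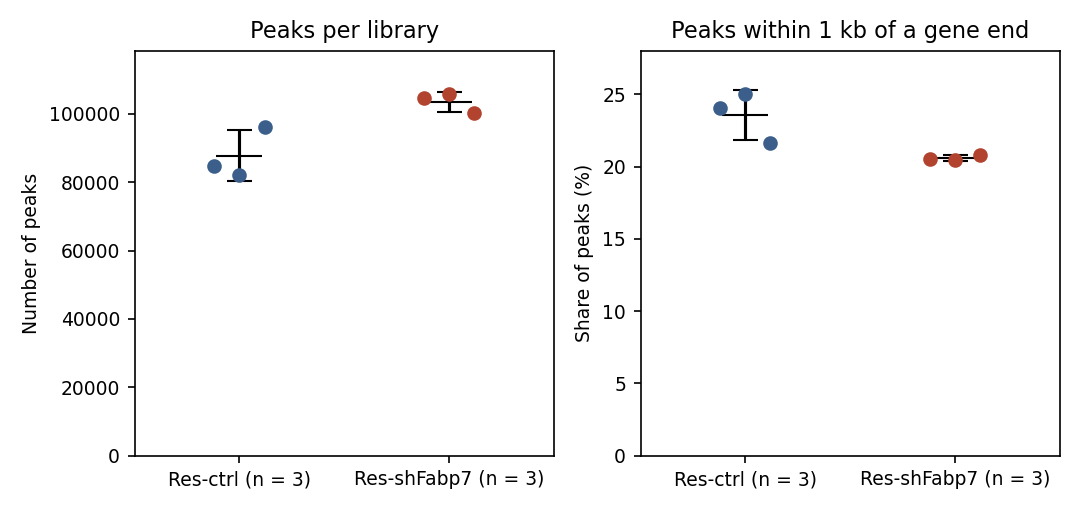
The left panel plots the number of peaks per library and the right panel the share of peaks within 1 kb of either end of a protein-coding gene, in percent. Each point is 1 library, and the bars show the mean and SD of 3 libraries per group. The Res-shFabp7 libraries lie above the Res-ctrl libraries for peaks, with means of 103538 and 87769, and below them for the share, with means of 20.6% and 23.6%.

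The open regions common to all libraries included the genes of a T cell. Of 134174 merged regions, 56610 (42.2%) were called in all 6 libraries. All 18 genes of the CD8 T cell identity list had such a region, and this list had 269 of its 520 regions in all 6 libraries. Bcl11b, a transcription factor of T cell commitment, had 37 such regions and Runx3, a transcription factor of the CD8 lineage, had 25. Cd8b1 had 12 and Cd8a 7. Effector and checkpoint genes were open as well. Ifng, the effector cytokine interferon gamma, had 19 regions in all 6 libraries, Il2ra 20, Gzmb 7 and Pdcd1 8. Tcf7, a transcription factor of naive and memory cells, had 20, Tox 29 and Arntl, a core clock gene, 9. All 13 CD4 and regulatory T cell markers had such a region too. Such a region was not particular to T cell genes, as 13904 of all 21887 genes had 1. All 28 apoptosis genes and all 23 chromatin modifiers did as well. For the markers of other cell types the part was smaller than for the T cell lists. Of the 12 NK cell markers 5 had a region in all 6 libraries, as did 12 of 15 B cell markers, 12 of 19 myeloid markers, 6 of 13 erythroid and megakaryocyte markers and 8 of 18 epithelial tumour markers. No region was assigned to the B cell gene Ms4a1, the lung epithelial gene Sftpc or the keratin gene Krt8.

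Overlap of open sequence was on average higher within groups than between them, but not for Res-ctrl replicate 3. The mean Jaccard index was 0.705 over the 3 pairs within Res-shFabp7, 0.686 over the 3 pairs within Res-ctrl and 0.662 over the 9 pairs between groups. The mean within groups exceeded that between groups by 0.0336 (one-sided exact permutation p = 0.1, the smallest possible). Res-ctrl replicate 3 overlapped each Res-shFabp7 library more (0.696, 0.692 and 0.702) than Res-ctrl replicates 1 and 2 (0.687 and 0.678). Without it the difference was 0.0576. The other 6 pairs between groups lay at 0.636 to 0.659, and the pair of Res-ctrl replicates 1 and 2 at 0.694.

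A total of 3065 regions were called only with Res-shFabp7 and 208 only with Res-ctrl. The regions called only with Res-shFabp7 with the strongest peaks were near Ext1, which acts in heparan sulfate synthesis (chromosome 15, 53000060 to 53000458, 68002 bp outside the gene), within Ide, the insulin-degrading enzyme (chromosome 19, 37293191 to 37293465), near Wwox, and within Camk4, a calcium-dependent kinase of T cell signalling (chromosome 18, 32993053 to 32993261). Their lowest −log10 q over the 3 libraries was 14.8, 14.7, 14.7 and 14.7, and the authors' fold over background was 9.38, 10.2 and 9.70 for the Ext1 region and 11.8, 9.63 and 11.2 for the Ide region. Grap, Ints6, Foxp2, Ism1, Kctd1 and Klhl22 completed the 10 genes of this direction, with a lowest −log10 q down to 13.4. The strongest regions called only with Res-ctrl were near Pls3 (chromosome X, 75729656 to 75729776) and 271 bp outside P4ha1, a collagen prolyl hydroxylase (chromosome 10, 59322885 to 59322968), with a lowest −log10 q of 10.3 and 10.0. Itpkb, Fam193b, Inpp5b, Tmprss6, Adgre5, Vps26c, Mrto4 and Clec16a followed, down to 7.73. All 20 of these regions were also specific to their group when each library was limited to its 82153 strongest peaks. They were picked for strong peaks: of the regions named from the gene lists below, 11 of 77 called only with Res-shFabp7 and 9 of 12 called only with Res-ctrl were. Shortening a list only removes peaks, so staying specific reflects the strength of a region's own peaks. It cannot test whether depth left the other group without a peak. The bar was also lower for Res-ctrl, whose replicate 2 list was not shortened. A Themis region called only with Res-ctrl stayed at a lowest −log10 q of 2.39, and a Tox region called only with Res-shFabp7 did not at 5.25.

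The imbalance depended on the length of the lists. With equal numbers of peaks, 1230 regions were called only with Res-shFabp7 and 573 only with Res-ctrl. Of the 3065 and 208 regions above, 707 and 133 were again specific. The other regions among the 1230 and 573 lay in merged regions that held a peak of the other group before the lists were shortened. Counts per list with equal numbers of peaks, given below, can include such regions. Leaving out 1 library relaxes the criterion and gave 3896 to 6987 and 416 to 758 regions, the 6987 without Res-ctrl replicate 3.

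**Figure D2:**
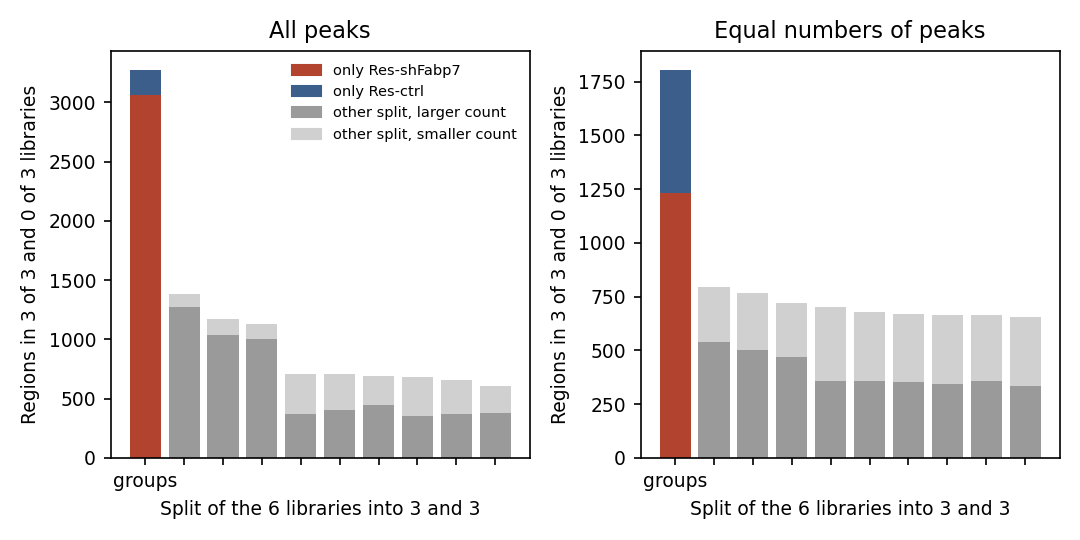
The bars show the number of regions with a peak in 3 of 3 libraries of one side and 0 of 3 of the other, for each of the 10 ways to split the 6 libraries into 3 and 3, from all peaks (left) and from the 82153 strongest peaks of each library (right). The first bar is the split by group, with 3065 and 208 regions on the left and 1230 and 573 on the right. The other 9 splits, in grey and sorted by total, reach at most 1382 and 796 regions in total.

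At effector genes, Ifng had 1 region called only with Res-shFabp7, on chromosome 10 from 118451797 to 118452187, outside the gene and 6098 bp from its end. The authors' fold was 6.78, 7.39 and 6.94 in the 3 libraries. Gzmb, a cytotoxic protease, had 1 on chromosome 14 from 56291421 to 56291608, 29180 bp from the gene, with folds of 4.35, 5.44 and 4.88. Both were also specific with equal numbers of peaks, which rests on the strength of their own peaks. Zeb2, a transcription factor of terminal effector cells, had 2 regions called only with Res-shFabp7, neither of them specific with equal numbers. Cx3cr1, a chemokine receptor of effector cells, had 1 region called only with Res-ctrl, on chromosome 9 from 120056248 to 120056529 within the gene, which was specific with equal numbers as well. In the whole cytotoxic effector list the counts were 8 and 1 (here and below, only Res-shFabp7 and only Res-ctrl), and 4 and 2 with equal numbers of peaks. The 8 and 1 were out of 377 regions, and over all merged regions the shares were 2.28% and 0.155%. The net count, only Res-shFabp7 minus only Res-ctrl, was 7, and matched random gene lists gave a median of 7. In the exhaustion and checkpoint list the counts were 9 and 0, with 3 regions at Cblb, a ubiquitin ligase that restrains T cell activation, and 2 each at Tox and Cd200r1. This list holds 420 regions. It had 3 and 1 with equal numbers of peaks, and none of the named regions at Cblb, Tox and Cd200r1 was specific. Pdcd1 and Tcf7 had no group-specific region.

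**Figure D3:**
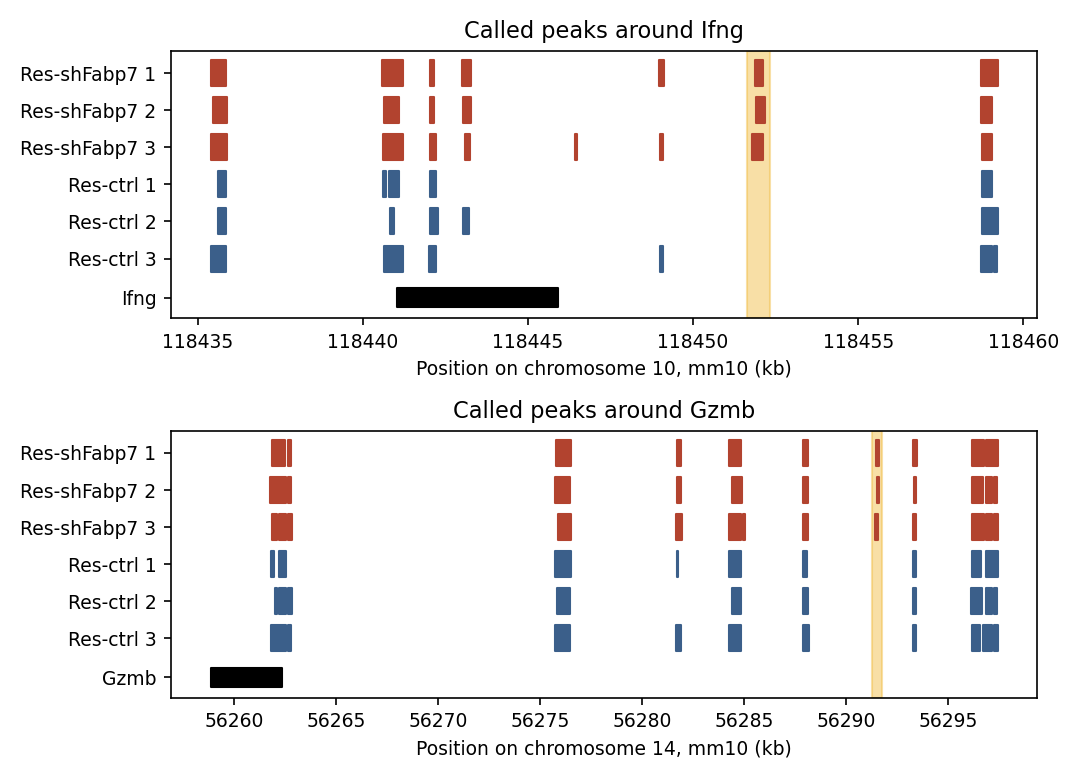
Each row shows the peaks called in 1 library, as boxes to scale along the chromosome in kb, with the gene in black, around Ifng (top) and Gzmb (bottom). The yellow bands mark the regions from 118451797 to 118452187 and from 56291421 to 56291608, which had a peak in 3 of 3 Res-shFabp7 libraries and 0 of 3 Res-ctrl libraries.

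The naive and memory list had regions in both directions, 16 and 4 of 1136, and 11 and 8 with equal numbers of peaks. Lef1, a transcription factor of naive T cells, had 3 regions called only with Res-shFabp7 within the gene and 2 called only with Res-ctrl just outside it, from 131107321 to 131107447 and from 131109957 to 131110050 on chromosome 3. Bach2, a repressor that restrains effector differentiation, had 2 regions within the gene on chromosome 4, from 32330652 to 32330816 and from 32331614 to 32331833, called only with Res-shFabp7. Foxp1 had 3 regions called only with Res-shFabp7, while Foxo1 had 1 called only with Res-ctrl. Of these, both Bach2 regions, 1 of 3 at Lef1 and 1 of 3 at Foxp1 called only with Res-shFabp7 and both Lef1 regions called only with Res-ctrl were specific with equal numbers of peaks, and the Foxo1 region was not. Among activation transcription factors the counts were 10 and 2 of 592, with 3 regions at Runx1 and 2 each at Myc and Nfkb1 against 1 each at Nfatc1 and Irf4. They were 2 and 3 with equal numbers of peaks, and the regions at Nfatc1 and Irf4 were specific while those at Runx1, Myc and Nfkb1 were not. In the CD8 T cell identity list they were 8 and 1, with regions at Gata3, Themis and Thy1, and 2 and 3 with equal numbers, where of these only the Themis region called only with Res-ctrl was specific.

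Metabolic, death and other lists had 2 to 8 regions called only with Res-shFabp7. They hold 244 regions for ferroptosis, 237 for fatty acid uptake and metabolism, 386 for apoptosis and 331 for circadian clock. Glycolysis and hypoxia holds 243, mitochondrial respiration 131, interferon response 155 and chromatin modifiers 350, so raw counts are not alike across lists. The ferroptosis list had 3 and 2. Slc7a11, the cystine transporter, Por and Acsl4 had 1 region each called only with Res-shFabp7. Lpcat3, which inserts polyunsaturated fatty acids into phospholipids, and Pcbp1, an iron chaperone, had 1 each called only with Res-ctrl, on chromosome 6 from 124688728 to 124688851 and from 86526142 to 86526324. The ferroptosis counts became 0 and 2 with equal numbers of peaks, as the regions at Lpcat3 and Pcbp1 were specific and those at Slc7a11, Por and Acsl4 were not. Fatty acid uptake and metabolism had 8 and 0, with 2 regions at Ppard and 1 each at Acadl and Pparg. Apoptosis had 7 and 1, with 2 at Bcl2l11 against 1 at Bcl2. Circadian clock genes had 7 and 0, with 2 each at Nfil3 and Arntl and 1 at Nr1d1. Glycolysis and hypoxia had 5 and 0, with 2 at Hif1a, mitochondrial respiration 2 and 0, interferon response 5 and 0, with 2 at Rsad2, and chromatin modifiers 5 and 1, the latter at Tet3. From equal numbers of peaks the counts were 2 and 1 for fatty acid uptake and metabolism, 3 and 3 for apoptosis, 2 and 1 for circadian clock, 2 and 0 for glycolysis and hypoxia, 0 and 0 for mitochondrial respiration, 1 and 0 for interferon response and 0 and 3 for chromatin modifiers. Of the regions at genes named here, those at Acadl and Tet3 and 1 of 2 each at Nfil3, Hif1a and Rsad2 were then specific, and those at Arntl, Nr1d1, Ppard, Pparg, Bcl2l11 and Bcl2 were not.

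Among markers of other cells, B cell markers had 3 and 0 with regions at Ebf1 and Blnk, myeloid markers 3 and 0, NK cell markers 1 and 0, CD4 and regulatory T cell markers 7 and 0, erythroid and megakaryocyte markers 0 and 0, and epithelial tumour markers 5 and 0 with 2 at Epcam. B cell and myeloid markers each had 3 and 0 with equal numbers of peaks, while NK cell markers, CD4 and regulatory T cell markers and epithelial tumour markers each had 0 and 1, and erythroid and megakaryocyte markers 0 and 0. The named regions at Ebf1, Blnk and Epcam were then not specific. Of those in the myeloid list, the region at S100a9 was specific and those at Mpo and Spi1 were not.

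Counts per list moved with other rules too. Where peaks had to cover 50% of a region, they were 13 and 1 for cytotoxic effector, 14 and 0 for exhaustion and checkpoint, 28 and 4 for naive and memory, 13 and 1 for activation transcription factors, 6 and 3 for apoptosis, 8 and 0 for interferon response, 10 and 1 for chromatin modifiers, 12 and 1 for CD4 and regulatory T cell markers and 0 and 0 for NK cell markers. At a q of 0.001 they were 3 and 2 for apoptosis, 8 and 1 for activation transcription factors, 1 and 0 for mitochondrial respiration, 7 and 0 for CD8 T cell identity and 0 and 0 for NK cell markers. When peaks were merged across 200 bp or counted by summit windows, 112 and 101 regions were called only with Res-ctrl, and the ferroptosis, activation transcription factor, chromatin modifier and CD8 T cell identity lists had 0 of them.

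Set against the 3065 to 208 of all regions, 0 of the 19 lists differed in direction (Fisher's exact test, lowest adjusted p = 0.336). From all peaks this test could find only a lean to Res-ctrl. The largest list, with 16 and 4 group-specific regions, was too small to pass toward Res-shFabp7 even with 0 on the Res-ctrl side. Before adjustment 2 lists had a p under 0.05, both with a larger part on the Res-ctrl side, naive and memory (Fisher's exact p = 0.0343) and ferroptosis (Fisher's exact p = 0.0354), and neither did with equal numbers of peaks (Fisher's exact p = 0.331 and 0.101), where chromatin modifiers, with 0 and 3, had an unadjusted p of 0.0320 (adjusted p = 0.608). With 2 of 3 libraries required in place of 3, CD8 T cell identity passed, with 21 and 11 regions (Fisher's exact test, adjusted p = 0.0344).

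The share of each library's peaks at the list genes was compared next. Peaks at CD8 T cell identity genes made up 3.89 ± 0.124 per 1000 with Res-shFabp7 and 4.28 ± 0.0391 with Res-ctrl (SD, n = 3 each). The values at naive and memory genes were 8.15 ± 0.204 and 8.81 ± 0.046, at apoptosis genes 3.00 ± 0.118 and 3.32 ± 0.1, and at circadian clock genes 2.40 ± 0.0541 and 2.49 ± 0.0204. The share at B cell markers was 0.537 ± 0.0248 with Res-shFabp7 and 0.437 ± 0.0229 with Res-ctrl, at myeloid markers 0.873 ± 0.0269 and 0.816 ± 0.0114, and at epithelial tumour markers 0.544 ± 0.0213 and 0.472 ± 0.0263. In these 7 of 19 lists the groups did not overlap, each with an exact permutation p of 0.1 and an adjusted p of 0.271, and chance gives this in 10% of lists, or 1.9. With equal numbers of peaks the groups were separated in 4 of them, each with an adjusted p of 0.475. The differences per 1000 peaks, Res-shFabp7 minus Res-ctrl, were then -0.203 in place of -0.387 at CD8 T cell identity genes, -0.158 in place of -0.329 at apoptosis genes, -0.450 in place of -0.660 at naive and memory genes and 0.0771 in place of 0.101 at B cell markers. In the lists no longer separated they were -0.00406 in place of 0.0564 at myeloid markers, 0.0243 in place of 0.0720 at epithelial tumour markers and -0.0933 in place of -0.0851 at circadian clock genes. Without Res-shFabp7 replicate 3 the groups were separated in 13 lists, where chance separates 2 against 3 libraries in 2 of 10 splits and 3 against 3 in 2 of 20.

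Peaks lay less often at gene ends with Res-shFabp7. Within 1 kb of either end of a gene were 20.6 ± 0.188% of peaks with Res-shFabp7 and 23.6 ± 1.73% with Res-ctrl (SD, n = 3 each; two-sided exact permutation p = 0.1), and 22.9 ± 0.31% and 24.3 ± 0.832% with equal numbers of peaks (exact permutation p = 0.1). Against Res-ctrl replicate 3 alone the difference was -1.07 percentage points, in place of -2.98. Peaks moved by 1 Mb as a background gave 4.21% to 4.38% in the 6 libraries. Of the regions called only with Res-shFabp7, 258 of 3065 lay at a gene end, which is 8.42% (95% Wilson interval 7.49 to 9.45), against 42 of 208 or 20.2% (15.3 to 26.2) of those called only with Res-ctrl (Fisher's exact p = 3.5e-07) and 24.3% of the regions in all 6 libraries. With equal numbers of peaks the shares were 7.24% and 16.8% (Fisher's exact p = 2.0e-09). Regions are not independent replicates, so both Fisher p-values describe these 6 libraries and do not test the groups. From all peaks, a split that mixed the groups came close to their contrast (log odds ratio -0.959 and -1.01), as given below.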

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

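All settings below except the strongest 40000 and 20000 peaks, Res-ctrl replicate 3 alone, a gene distance of 20 kb and the height ranks were chosen before the data were examined. The differences in peak number, overlap and gene-end share kept their direction in all settings run, but with 3 against 3 libraries their p could not pass 0.05, so this says nothing of significance. Without 1 library, the difference in peaks was 12961 to 20040, in the Jaccard index 0.0267 to 0.0576 and in the gene-end share -3.94 to -2.26 percentage points. Regions called only with Res-shFabp7 numbered 3896 to 6987 and only with Res-ctrl 416 to 758, higher because fewer libraries were required, and 7 to 13 lists were separated, which chance gives in 2 of 10 splits in place of 2 of 20. With equal numbers of peaks the values were 1230 regions, 573 regions and 4 lists, with the strongest 40000 peaks 680, 324 and 3, and with the strongest 20000 peaks 309, 176 and 5. Requiring 2 of 3 libraries gave 9768 and 1481 and 1 list with a direction (adjusted p = 0.0344; 0.0344 to 1 over the settings). Merging across 200 bp gave 112 and summit windows 101 regions only with Res-ctrl; the cause was not tested. Against Res-ctrl replicate 3 alone the gene-end difference was -1.07 percentage points and the counts were 5583 and 5906, where the second needs 1 library and the first 3, so they are not alike. Stricter q, 50% coverage and all sequences moved neither total of group-specific regions by over 1.5 times (3777 and 239 with 50% coverage, 2844 and 212 at a q of 0.001), but counts of single lists moved by more with 50% coverage (naive and memory from 16 to 28, chromatin modifiers from 5 to 10) and at a q of 0.001 (apoptosis from 7 to 3). The height ranks called 444 to 2829 regions without 1 library, 1380 in the upper part by height, 284 with gene ends and other regions ranked separately in 1 fit, 149 against Res-ctrl replicate 3 alone, 1 without the trend and 0 with ranks of fold; the cause was not tested.

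Replicate numbers did not pair the samples: the correlations of the deviations of same-numbered libraries were -0.0245, 0.015 and -0.0158. With the replicate block the difference in peaks was 15769 and in gene-end share -2.98 percentage points, each with the smallest exact sign-flip p of 0.25, 13 lists kept 1 direction in the 3 pairs (by chance 1 in 4) and the height ranks called 2678 regions.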

Other observations

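All explanation tests in this part were chosen after the results were seen. The genes with the most regions called only with Res-shFabp7 were outside the fixed lists and were picked after their values were seen. Arid1b, a subunit of a chromatin remodelling complex, had 7 of its 97 regions called only with Res-shFabp7, Maml2, a Notch coactivator, had 6 of 105, and Fars2, Nfia, Elmo1, Celf2, Wwox and Lpp had 5 each. With Res-ctrl, Adgre5, Abr, Fyb and Lef1 had 2 each. None of 16229 genes held more such regions than its number of regions gives by chance (hypergeometric test, lowest adjusted p = 0.679 for Res-shFabp7 and 1 for Res-ctrl, with 359 and 145 genes at an unadjusted p under 0.05).

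The excess of regions called only with Res-shFabp7 over those called only with Res-ctrl is what a difference in depth could give. With equal numbers of peaks the ratio of the counts was 2.15, and the other splits that keep Res-ctrl replicates 1 and 2, the libraries of lowest background, on 1 side reached 2.12. The split with 2.12 differs more in mean background between its sides (0.269) than the groups do (0.177). The others gave 1.87 and 1.91 at differences of 0.163 and 0.208. From all peaks the ratio was 14.7 for the groups and at most 11.8 for these splits. The total of group-specific regions is another matter: at 1803 with equal numbers of peaks it was 2.27 times the highest total of those splits, 796, so depth as read from the background is not the whole source of the total. In 1 of the 10 splits, the real one, the total from all peaks was as large, with 3273 against at most 1382, and 10 splits are too few for a share under 0.05. Reads from other cell types stay open: 12 of 3065 regions called only with Res-shFabp7 and 337 of 131109 other regions lay at genes of the B cell, NK cell, myeloid, erythroid or epithelial lists, an odds ratio of 1.53 (95% interval 0.857 to 2.72, Fisher's exact p = 0.148), although the labels describe removal of other cells and a membrane before the tumour cells, and some of these genes are open in T cells too. The pooled test does not show the lists apart. Epithelial tumour markers alone had 5 of 68 regions called only with Res-shFabp7, and 0 with equal numbers of peaks.

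The lower gene-end share of the regions called only with Res-shFabp7 was weighed against depth in the same way. From all peaks, a split that puts Res-ctrl replicate 3 with Res-shFabp7 replicates 1 and 2 gave 10.8% on the deeper side and 24.1% on the other, close to the 8.42% and 20.2% of the groups (log odds ratio -0.959 and -1.01), and the other 2 splits that keep the libraries of lowest background together gave 9.83% and 16.0% (-0.561) and 10.0% and 19.1% (-0.752). With equal numbers of peaks the log odds ratio was -0.948 for the groups and -0.177, -0.121 and -0.519 for the 3 splits that keep the libraries of lowest background together. The difference from the nearest of them was -1.56 standard errors, and from the other two -2.97 and -2.94, so depth and the culture condition cannot be told apart for this share. A candidate biological explanation, that T cells cultured with Res-shFabp7 open more regions away from gene ends, was not tested apart from library quality, which would need the reads, and GC content was not analysed here.

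A comparison of peak heights gave calls that came and went with the setting. Over the 56610 regions called in all 6 libraries, limma on normal scores of the height ranks called 1538 regions higher and 674 lower with Res-shFabp7 at an adjusted p under 0.05, 2212 in total, and quantile-normalised log2 heights, tried first, called 1773 and 792. Ranks of fold called 0, with 7771 regions at an unadjusted p under 0.05 against 10832 for the heights, and limma without the trend called 1, with 8867. With gene ends and other regions ranked separately, 1 joint fit called 284 and separate fits, tried after the joint one was seen, called 2045. Without Res-shFabp7 replicate 1 it called 444, without replicate 2 1011 and without replicate 3 732, and without Res-ctrl replicate 1 980 and without replicate 2 1364. The real split was the 1 of 10 with as many calls, and the other 9 called 0, with 1391 to 3687 regions at an unadjusted p under 0.05; 10 splits are too few for a share under 0.05. Of the 19 lists, activation transcription factors had the only called share that passed against all other regions, with 16 of 267 regions higher and 6 lower, or 8.24% called (Fisher's exact test, adjusted p = 0.0222), and no list passed for direction (lowest adjusted p = 0.15). Its 16 and 6 became 3 and 1, 5 and 2, and 3 and 3 without Res-shFabp7 replicates 1, 2 and 3, 6 and 3, 7 and 2, and 20 and 5 without Res-ctrl replicates 1, 2 and 3, 1 and 0 against Res-ctrl replicate 3 alone, 1 and 1 with gene ends ranked separately in 1 fit, 10 and 7 with separate fits, and 0 and 0 with ranks of fold or without the trend. By gene, Atxn1, F13a1, Ifng, Cd47, Pax5 and Slc7a5 held more regions called higher than their number of tested regions gives by chance (hypergeometric test, adjusted p = 0.0101 to 0.0412). Regions of 1 gene are not independent. The cytotoxic effector list had 14 of 179 regions called higher and 0 lower, or 7.82% called against 2.72% called higher and 1.19% lower of all regions. Of the 14, 6 lay at the single gene Ifng. The list did not pass Fisher's exact test (adjusted p = 0.126 for the called share and 0.15 for direction). It passed camera with a preset correlation (camera adjusted p = 0.0025, and 0.0043 with gene ends and other regions ranked separately). With an estimated correlation it did not (camera adjusted p = 0.379), and no list passed. B cell markers had 4 of 27 higher, 3 of them at Pax5, and 0 lower (Fisher's exact test, adjusted p = 0.126 for the called share). The 14 became 2, 6 and 5 without Res-shFabp7 replicates 1, 2 and 3, 4, 9 and 19 without Res-ctrl replicates 1, 2 and 3, 1 against Res-ctrl replicate 3 alone, 15 with separate fits, and 0 with ranks of fold, without the trend, and with gene ends ranked separately in 1 fit. Whether regions at effector genes gained height may be worth a test on read counts, and it stays a hypothesis, since ranks of fold gave 0 calls.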
